A study of Mus musculus with 2 samples.

How the data were processed

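m6A immunoprecipitation sequencing (MeRIP-seq) was performed on pancreatic islets of 2-week-old 129sv mice. In this assay fragmented RNA is pulled down with an antibody against N6-methyladenosine (m6A) and sequenced next to an aliquot of the same kind of RNA that was not pulled down, the input. Per the labels there was 1 m6A immunoprecipitate library and 1 input library. With 1 library per group there are no replicates, so no test across samples, no error and no p-value of its own accompanies any value.

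Per the labels, the authors trimmed reads with cutadapt 1.9.3, aligned them with HISAT2 2.0.4, called sites with MACS and assigned the sites to transcripts with their own scripts. The labels name 2 genome builds, human UCSC HG19 in the library protocol and mouse mm10 in the processing notes. To settle this, sites were set against gene spans of GRCm38.p6, the assembly that mm10 corresponds to. Of the 8942 sites whose gene could be matched, 8924 (99.8%) overlapped the span of the gene they were assigned to, so coordinates are given as GRCm38. The match used the gene identifier for 8822 sites and the symbol or a synonym for the rest; 45 sites were not matched.

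The authors' deposited table gives a chromosome, start, end and length for each site, and 3 values from the peak caller. The deposited score is the negative log10 of the caller's p, times 10, so a score of 100 stands for a p of 1e-10. The deposited fold enrichment is a linear ratio of the immunoprecipitate over the background that the caller expects from the input. The deposited FDR was read from its name and values as the caller's false discovery rate in percent; how it was computed is not given in the sources used here. These are the authors' own values, were not recomputed, and were compared only within the list, by rank, by medians and in stricter limits. End minus start equalled the length in all 8987 sites, so starts were read as counted from 0 and are printed counted from 1. No reads or counts per gene were used, so the depth of both libraries and the input level of each gene are unknown here. The list may hold only part of the sites that were called, since the peak numbers run up to 90659. A gene without a site is therefore described as having no site in the list analysed here, never as unmethylated.

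Each unique interval was counted as 1 site. No interval occurred more than once. For each of 19 gene lists, fixed before the data were examined, the share of genes with at least 1 site was compared with 10000 random lists of the same size from all 21900 protein-coding genes of the RefSeq annotation. The design asked for random lists matched on transcript length. Transcript lengths were not given, so unmatched lists were used, as the design provided, and a comparison with random lists matched on genomic span in 20 bins was added after seeing the data. For lists with at least 3 genes with a site, the median of the strongest fold per gene was compared with 10000 random lists drawn from genes with a site. A list is called higher or lower where it lies above percentile 97.5 or below percentile 2.5 of the random lists. This describes 1 site list and is not a test across animals. A gene too low in the input cannot have a site, and the random lists for the shares were drawn without regard to expression. All 461 list entries, 452 distinct genes, matched the annotation. The lists cover islet transcription factors, beta cell secretory genes, beta cell maturation, other endocrine cells, acinar, duct, endothelial, leukocyte, fibroblast and glial markers, m6A machinery, insulin and IGF signalling, cell cycle, the unfolded protein response, genes disallowed in beta cells, early response genes, chromatin regulators, ribosomal proteins and oxidative phosphorylation.

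On simulated lists, a share of 60% planted in a list of 28 genes was called in 19 of 20 runs over 21900 genes, and an unplanted list in 0 of 20. Folds multiplied by 2 in a list of 20 genes were called in 20 of 20 runs over 4953 genes, and an unplanted list in 1 of 20. The simulations shuffled sites and folds among genes, which removes any link to gene span or input level. They therefore do not show how often such links lead to a call, nor how shorter lists behave.

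The rule for named genes was also fixed before the data were examined. It takes the 10 genes with the largest fold, the 5 genes with the most sites, and from each list every gene with a site when there are 4 or fewer, otherwise the 4 with the largest strongest fold, with up to 4 genes without a site in the order of the list. Mafa, Pdx1, Ins1, Ins2, Gcg, Mettl3 and Mettl14 are named in any case. Not every gene that the rule takes is printed. Alternatives were a stricter fold of at least 5, a stricter p of at most 1e-10, merged overlapping intervals, the median in place of the strongest fold per gene and random lists matched on the number of sites. Limits on the FDR and on the overlap with the gene span were added after seeing the data. The place of sites along transcripts and the DRACH motif were planned but not analysed, because exons, strand and sequence were not used here. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9.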

Results

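Islets from 2-week-old mice, an age before weaning when beta cells are still maturing, were profiled for m6A, the most abundant internal modification of messenger RNA. The data are 1 list of sites enriched in the m6A immunoprecipitate over the input, 1 library each. There are no replicates, no second age or genotype in the comparison, and no read depth to set the precision of a site. Folds, scores and false discovery rates are the authors' own, from their deposited table. Coordinates are GRCm38, counted from 1.

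The comparison of immunoprecipitate with input asks which transcripts of young islets carry m6A. Mafa, a transcription factor of mature beta cells, was among the enriched transcripts, with a fold of 12.52. So were the secretory granule proteins Chga (fold 27.48) and Chgb (fold 21.38), and Mettl14, a subunit of the m6A methyltransferase. The insulin genes Ins1 and Ins2, the glucagon gene Gcg, the pancreatic transcription factor Pdx1 and the catalytic methyltransferase subunit Mettl3 had no site in the list analysed here. In all, 8987 sites lay on 4953 genes. The median fold was 7.13, with quartiles of 5.47 and 9.87 and a range from 2.19 to 449.81. Sites had a median length of 211 bases, with quartiles of 139 and 449 bases.

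The caller's own false discovery rate was high throughout. It was 100% for 6677 sites (74.3%), below 100% for 2310 and below 50% for 437, and its lowest value was 27.16%, so 0 sites passed a limit of 5%. The score ran from 50 to 3208.2, and 119 sites, with a median fold of 20.25, shared the value 3100. Above it lay 4 sites, named after their values were seen, on Cald1, Chgb, Myo18a and Nsrp1. Their rates were 33.33% for Chgb and 100% for the other three. Whether 3100 is an upper limit of the score, and how the rate was computed, is not given in the sources used here, so neither ranks the 119 sites among themselves.

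The Mafa site covered 1080 bases at chromosome 15, 75746843 to 75747922, within a gene that spans 75745501 to 75748321. Its score was 3100 and its false discovery rate 27.16%, values shared by all 119 of those sites, and its fold ranked at percentile 78.8 of the genes with a site. Mettl14 had 4 sites with folds from 5.8 to 10.25, each with a false discovery rate of 100%. The strongest lay at chromosome 3, 123380220 to 123380307.

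The largest folds fell on genes of several kinds. Rsph3b and Rsph3a, paralogous genes of the radial spoke of cilia, had folds of 449.81 (chromosome 17, 6941669 to 6941756) and 162.49 (chromosome 17, 7952549 to 7952636), each on a site of 88 bases. The predicted genes Gm4799, Gm10335, Gm10800 and Gm20594 had folds of 411.52, 116.15, 99.75 and 98.59; Gm10800 was not matched to the annotation, so its site was not placed on a gene span. Tmem38b, an intracellular cation channel, had a fold of 105.13 (chromosome 4, 53860482 to 53860947). Prkaca, the catalytic subunit of protein kinase A, had a fold of 81.77 (chromosome 8, 83972978 to 83973232). Gnb1, a G protein beta subunit, had a fold of 79.99 (chromosome 4, 155491361 to 155491580), and Bptf, a chromatin remodelling factor, a fold of 78.31 (chromosome 11, 107131274 to 107132127). All 10 sites had the score 3100. Whether reads at the Rsph3 and predicted genes map to a single place was not analysed.

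Genes with many sites included those of very large proteins. Syne2, a nuclear envelope spectrin-repeat protein, had 28 sites, Utrn (utrophin) 26, the cytoskeletal linker Dst 21, and Syne1 17. The strongest folds of these genes were 17.94, 17.5, 25.73 and 19.77. A single site was found on 2958 genes (59.7%), and 29 genes had 10 or more, with a mean of 1.81 sites per gene. Across genes with at least 1 site, which are not independent replicates, the number of sites rose with genomic span (Spearman rho 0.28). Among protein-coding genes, 22.2% had a site, from 2.05% in the shortest of 10 groups by span to 42.1% in the longest.

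**Figure D1:**
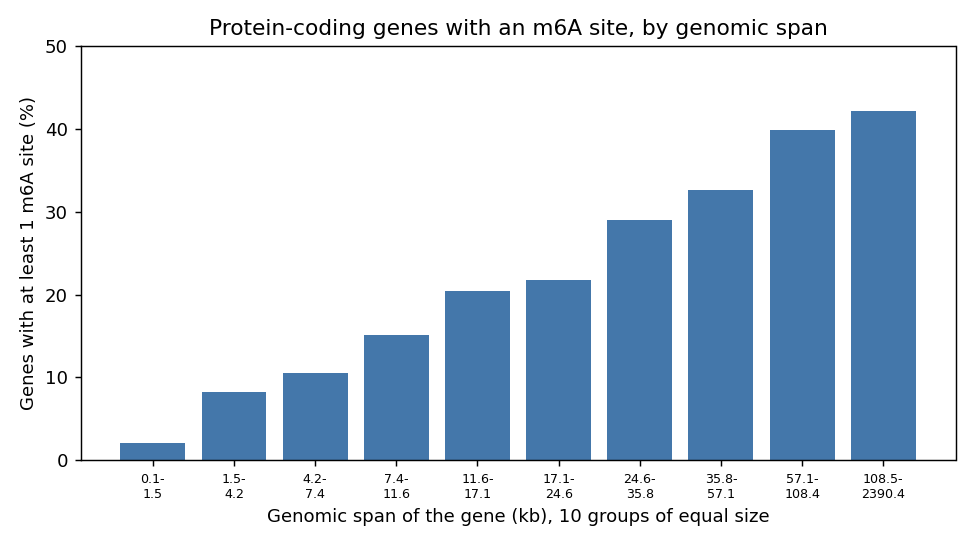
The horizontal axis gives 10 equal groups of protein-coding genes by genomic span in kilobases, and the bars the percentage of each group with at least 1 site. The percentage goes from 2.05% in the shortest group to 42.1% in the longest.

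Regulators of beta cell maturation carried sites more often than random protein-coding genes, which were not matched on input level. Of 22 genes in this list, 13 (59.1%) had a site, at percentile 99.99 of the random lists. The strongest were the growth kinase Mtor (fold 13.82, 7 sites), the calcineurin subunit Ppp3r1 (12.6), Mafa (12.52) and the histone methyltransferase Ezh2 (12.32). Ucn3, Syt4 and Esrrg were among the 9 genes without a site. With sites of a false discovery rate below 100% alone, the list fell to percentile 95.62 and was no longer called.

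Islet transcription factors and beta cell secretory genes stayed within the range of random lists. A site was found on 8 of 26 transcription factors (30.8%, percentile 85.36), the strongest on the motor neuron and beta cell factor Mnx1 (fold 13.08), the Wnt effector Tcf7l2 (12.95), Mafa (12.52) and the endocrine factor Neurod1 (9.24). Pdx1, Nkx6-1 and Nkx2-2 were among the 18 without one. Of 37 secretory genes, 11 (29.7%, percentile 85.39) had a site. Chga (27.48, chromosome 12, 102562598 to 102563073), Chgb (21.38), the granule chaperone Scg5 (18.1) and the calcium channel subunit Cacna1a (16.07) led them, while Ins1, Ins2, Iapp and Slc2a2 were among the 26 without a site. Of 15 markers of other endocrine cells, 4 (26.7%, percentile 67.88) had a site, among them Irx1 (19.06), Fev (6.24) and Gc (5.65). Gcg, Ttr and Irx2 were among the 11 without. The median strongest folds were 10.35 for maturation genes, 8.955 for transcription factors, 9.4 for secretory genes and 12.65 for other endocrine markers, all within the range of random lists.

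Chromatin regulators had the highest share of the 19 lists, with sites on 25 of 28 genes (89.3%). The central 95% of random lists ran from 7.14% to 39.3%, and from 21.4% to 57.1% when matched on genomic span. The remodellers Chd3 (27.99), Smarca4 (26.33, 10 sites) and Chd7 (24.42) were among the strongest, and Setd5, Arid2 and Kdm6a had no site. The median strongest fold was 12.24, at percentile 99.84. That call was not kept under 3 alternatives: with the median fold per gene the list lay at percentile 58.56, against genes with as many sites at 85.78, and with p of at most 1e-10 at 96.92.

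Insulin and IGF signalling and the m6A machinery were also above the random lists in share. Of 24 signalling genes, 14 (58.3%) had a site, at percentile 100, and at 98.53 when matched on genomic span. They were led by the kinase Akt1 (18.54), the PI3-kinase regulatory subunit Pik3r1 (17.29) and Mtor (13.82). Igf1r, Igf2, Irs1 and Pik3cb were among the 10 without. Of 22 genes that write, remove or bind m6A, 12 (54.5%, percentile 99.94) had a site. The nuclear reader Ythdc1 (30.85, 4 sites), the writer complex members Virma (28.02) and Zc3h13 (22.96, 8 sites) and the RNA-binding protein Fmr1 (19.98) were strongest, and Mettl3, Rbm15b, Cbll1 and Fto were among the 10 without. Median strongest folds were 7.69 and 9.635, both within the range of random lists.

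Genes of the endoplasmic reticulum and the unfolded protein response had sites on 10 of 19 members (52.6%, percentile 99.76). The protein disulfide isomerase Pdia4 had a fold of 53.43 (chromosome 6, 47813217 to 47813441), followed by the chaperones Hsp90b1 (18.2) and Calr (13.87) and the stress transcription factor Xbp1 (11.52). Ern1, Atf4, Hspa5 and Dnajb9 were among the 9 without a site, and the median strongest fold of 9.11 was within the random range. Genes normally silenced in mature beta cells, called disallowed, had a site on 7 of 13 (53.8%, percentile 99.16, and 97.71 matched on genomic span). The strongest were Igfbp4 (10.91), Arap2 (8.72), the hexokinase Hk1 (7.9) and catalase, Cat (7.35). Slc16a1, Ldha, Mgst1 and Oat were among the 6 without, and the median fold was 7.35. The share of disallowed genes was not called with p of at most 1e-10 (percentile 91.42) or a false discovery rate below 100% (percentile 18.82).

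Cell cycle and early response genes were not called against all genes. Sites lay on 7 of 23 cell cycle genes (30.4%, percentile 82.58), with the cyclin-dependent kinase inhibitor Cdkn1c (18.79), the topoisomerase Top2a (13.3), Myc (9.32) and Cdkn2c (5.96) strongest. Ccnd1, Ccnd2, Ccnd3 and Cdk2 were among the 16 without. Of 20 early response genes, which dissociation of a tissue can induce, 6 (30.0%, percentile 79.4) had a site, led by Jun (10.22), Myc (9.32), Jund (8.78) and Klf2 (7.66), and Fos, Fosb, Junb and Egr1 were among the 14 without. Matched on genomic span, the early response list was higher, at percentile 98.74. Median strongest folds were 5.96 for the cell cycle and 8.22 for early response genes.

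Some markers of other cells that islet preparations can hold carried sites, but which cells their RNA came from was not analysed. Endothelial markers had sites on 7 of 10 genes (70.0%, percentile 99.84), including the adhesion molecules Pecam1 (9.54) and Cdh5 (9.52), Plvap (8.08) and the VEGF receptor Flt1 (8.07), with none on Tek, Tie1 and Esam. Duct markers had sites on 5 of 10 (50%, percentile 96.86, 98.62 when matched on genomic span, and 77.9 with a fold of at least 5), with the keratins Krt8 (20.01), Krt7 (16.99) and Krt18 (7.78) and the factor Sox9 (4.63) strongest and none on Krt19, Spp1, Cftr and Muc1. Median strongest folds were 8.07 for endothelial and 7.78 for duct markers.

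Acinar markers had sites on 3 of 20 genes (15%, percentile 23.48), each with a fold below 5, among them amylase Amy2b at 2.98 and lipase Pnlip at 2.87. Their median of 2.98 lay at percentile 0 of the random lists, with 3 genes only. At a fold of at least 5 the list had 0 genes with a site, at percentile 0.58. Over all sites, the share lay at percentile 53.39 of random lists matched on genomic span. Cpa1, Cpb1, Prss1 and Prss2 were among the 17 without. Fibroblast and stellate cell markers had sites on 3 of 10 (30.0%, percentile 73.03), Col3a1 at 12.01, Vim at 5.01 and Pdgfrb at 4.39, with a median of 5.01, while Col1a1, Col1a2, Pdgfra and Acta2 were among those without. A single leukocyte marker of 10, the complement component C1qc (5.5), and a single glial marker of 8, Ncam1 (5.18), had a site, at percentiles 19.8 and 27.9. Ptprc, Cd68, Adgre1 and Csf1r, and Sox10 and S100b, were without.

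Short, abundant transcripts of ribosomal proteins and oxidative phosphorylation were not called against all genes but were higher when matched on genomic span. Sites were found on 22 of 78 ribosomal genes (28.2%, percentile 89.81, and 100 matched). Their share was also higher with p of at most 1e-10 (percentile 99.03) or a false discovery rate below 100% (percentile 99.98), but not with a fold of at least 5 (percentile 68.9). Rpl37 (17.6), Rps9 (16.62) and Rpsa (16.25) were strongest, and ribosomal genes have many processed copies in the genome that can share their reads. Of 66 oxidative phosphorylation genes, 18 (27.3%, percentile 83.94, and 99.64 matched) had a site, with the complex III subunit Uqcrh (19.99) and the complex I subunits Ndufa10 (18.04), Ndufa12 (15.11) and Ndufb9 (13.68) strongest. Median strongest folds were 7.22 and 7.38. Among the 19 lists, 7 were higher in share and 0 lower against all genes. The input level of the genes was not matched in any of these comparisons. A higher share can therefore reflect which genes are expressed, and does not by itself show preferential methylation.

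**Figure D2:**
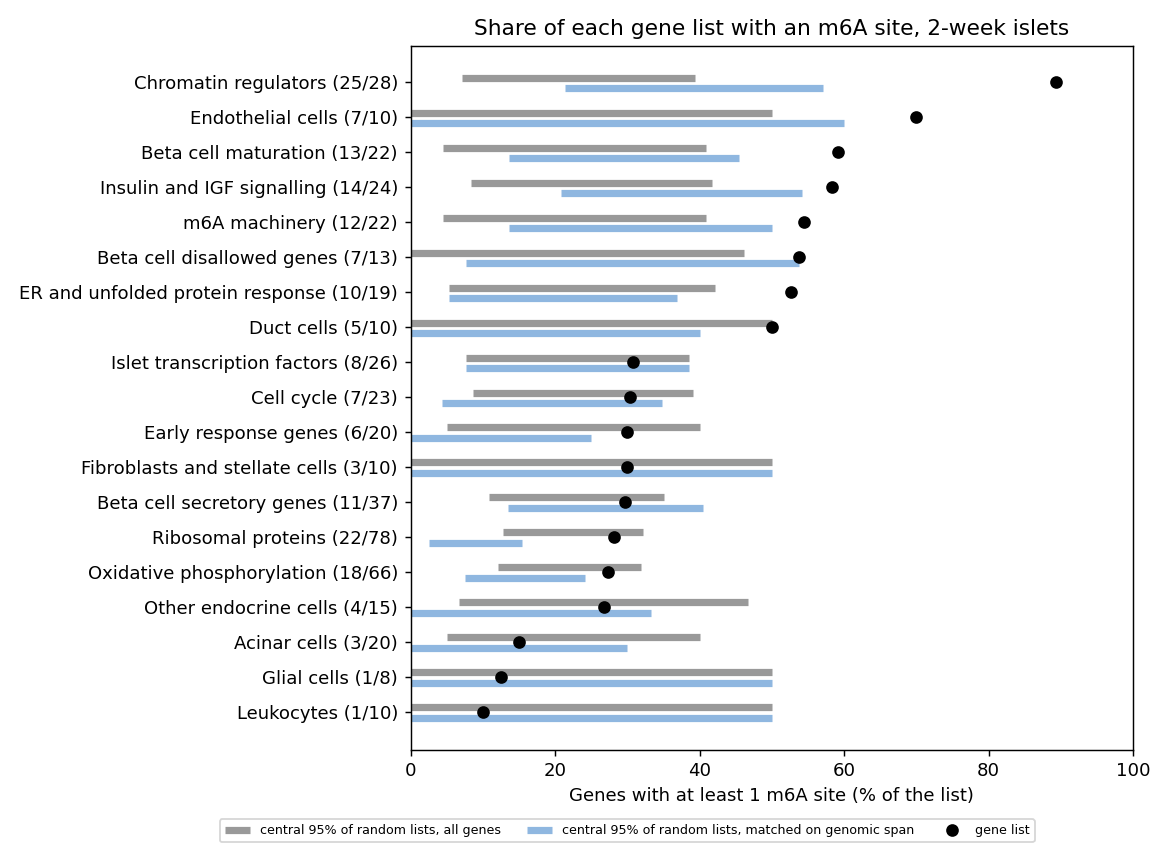
Each point is the percentage of a gene list with at least 1 site, grey bars the central 95% of 10000 random lists from all protein-coding genes, and blue bars that of random lists matched on genomic span. Chromatin regulators (89.3%) lie farthest from both ranges.

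**Figure D3:**
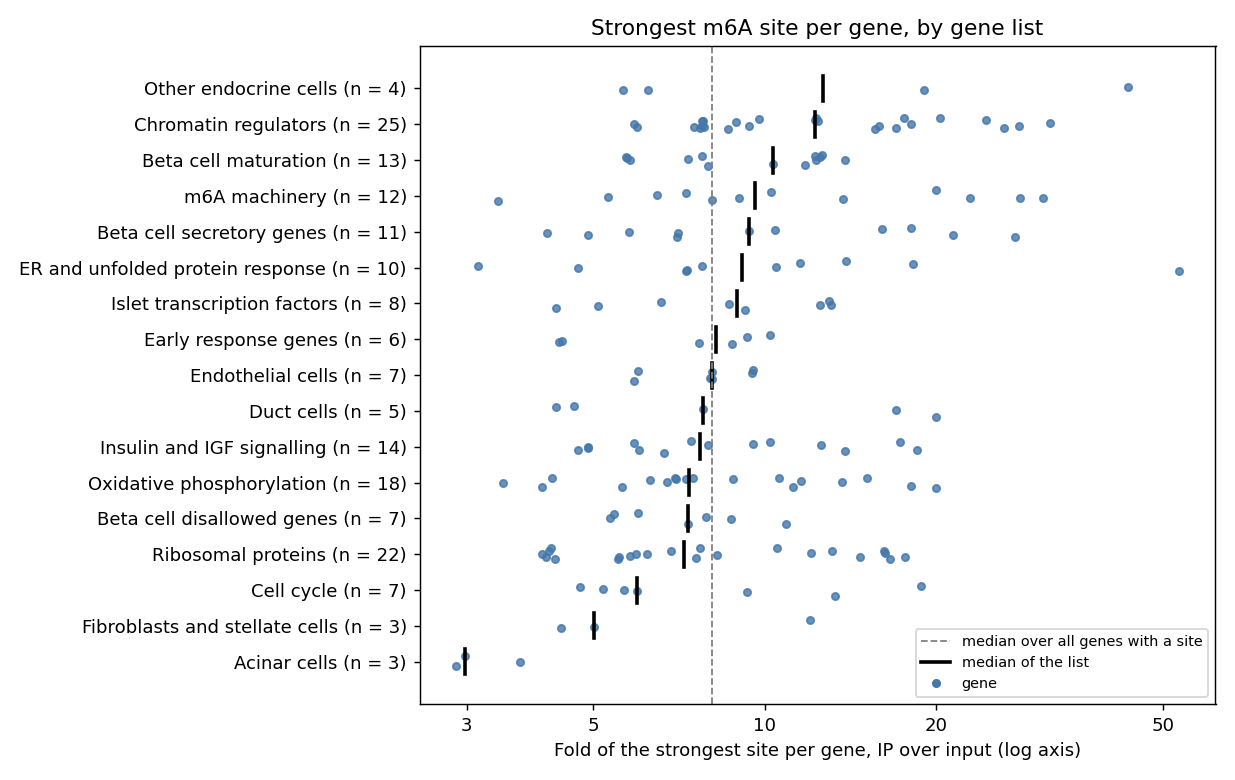
Each point is the fold of the strongest site of a gene on a log axis, for the lists with at least 3 genes with a site; black lines are list medians and the dashed line the median of 8.1 over all genes with a site. Acinar genes (median 2.98) lie lowest, and the highest point is Pdia4 at 53.43.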

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

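The FDR limits, the random lists matched on genomic span, the overlap with the gene span and the p limit for gene lists and sites per gene were chosen after seeing the data. With p of at most 1e-10 there were 5582 sites. With an FDR below 100% there were 2310 sites on 1635 genes with a median fold of 12.16, and below 50% there were 437 sites on 368 genes with a median fold of 16.99; these limits keep fewer sites by construction. With random lists matched on genomic span, 11 lists were higher in share in place of 7, the 4 added being duct markers, early response genes, ribosomal proteins and oxidative phosphorylation. With a fold of at least 5, 1 list was lower in share, the acinar markers. For the median strongest fold, 1 list was higher (chromatin regulators) and 1 lower (acinar markers). With the median fold per gene, with random lists matched on the number of sites and with p of at most 1e-10, 0 lists were higher, and with p of at most 1e-10, 2 were lower, the second being ribosomal proteins at percentile 1.815. The causes of these changes in list calls were not tested. Under the overlap with the gene span, 19 of 19 lists kept their call in share and 17 of 17 in fold. That limit removed only 18 matched and 45 unmatched sites of 8987, so it says little about stability. Merging overlapping intervals moved nothing because no intervals overlapped, so it says nothing about stability. Alternatives for the position along transcripts and for the DRACH motif were not run, and unmatched random lists were already the main choice. Read depth is unknown, so no site's fold carries an error.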

Other observations

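The authors' pathway annotation gives a further view of the strongest folds. Of 163 KEGG pathways with at least 15 genes with a site, 27 had a median strongest fold above the central 95% of 2000 random lists and 7 below it, where chance gives 4.08 on each side for independent pathways. Against genes with as many sites, 27 were above and 2 below, so the low side held no excess. The insulin secretion pathway had a median of 11.4 over 27 genes (percentile 99.6, and 99.52 against genes with as many sites). Pathways not tied to islets had higher medians, such as vasopressin-regulated water reabsorption (12.54), thyroid hormone synthesis (12.11) and gastric acid secretion (11.79). Genes of the insulin secretion pathway with large folds were Prkaca (81.77), the protein kinase A subunit Prkacb (30.69) and the calcium-dependent kinase Camk2b (20.3). The cAMP signalling pathway (63 genes, median 10.22, percentile 99.83) was also high, and many of the high pathways share these signalling genes, so they are not independent. Glycolysis and gluconeogenesis lay low, with a median of 5.7 over 15 genes (percentile 0.25, and 0.625 against genes with as many sites), including Gpi1 (3.54). These pathways were picked out after their values were seen.

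In what follows, the tests on site edges and on the largest folds were chosen after the results were seen. So was that of exonic length for the chromatin regulators. Those of genomic span and input level were set down before their own results were seen. The comparison matched on genomic span was itself added after seeing the data.

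Many sites ended exactly at the outer base of their gene. On 794 sites, 819 edges lay there, against 14.7 edges per base within 10 bases on either side. This argues against edges set by reads running out at the physical end of the RNA, which would scatter over nearby bases. Trimming of sites to annotated transcripts in the authors' mapping step is a candidate explanation that the 819 exact edges leave standing. No biological explanation was tested.

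The share of chromatin regulators with a site stayed above random lists matched on genomic span, at percentile 100, which argues against genomic span as the whole cause. The input level of these transcripts and their exonic length remain open, since 0 columns of the site table analysed here hold an input level and 0 columns of the gene annotation used here an exonic length. The design has no second group, so no biological explanation was tested.

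The 90 sites in the top 1% by fold, at 31.92 or more, had 3 explanations set against them. Their median deposited length was 310.5 bases (95% bootstrap interval 259 to 357.5, over sites), against 210 for the others. For the 90 sites as a set, this argues against short deposited length as the whole cause. It does not speak for single sites, as those of Rsph3b and Rsph3a had 88 bases each. Deposited lengths may differ from called lengths if sites were trimmed, and the number of input reads was not analysed. Position at an end of the gene goes with the largest folds. Of the 87 that overlapped their gene, 61 (70.1%) lay within 1000 bases of an end against 2725 of 8837 others (30.8%), a ratio of 2.27. Without strand the start and the end of a gene were not separated. A site on a gene shorter than 1000 bases, such as Gm4799, always lies near an end. The shares were not matched on gene span, so the ratio does not separate position from short genes. Reads shared between near-identical copies cannot be settled. Genes with a provisional Gm name held 8 of the 90 sites (8.89%) against 59 of 8897 others (0.663%), a ratio of 13.4. This difference was noticed in the pattern itself and does not show where reads map. No biological explanation was tested, since the design has a single group of islets.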
